A study of Mus musculus with 7 samples.

How the data were processed

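Total RNA from the soleus, a postural hindlimb muscle of the mouse, was measured on 7 one-colour Affymetrix arrays, 3 from wild type mice and 4 from mice labelled as Yy1 knockout. The animals were 6 months old and of a mixed C57Bl/6 and 129 background, per the labels. RNA was extracted with Trizol and turned into biotin-labelled cRNA by in vitro transcription, per the labels' protocols. Which part of Yy1 was removed, and in which cells, is not given in the sources used here.

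The authors deposited one intensity per probe set and array, and RMA (background correction, normalization between arrays and summary of the probes of a set) is named per the submitters' processing notes. The RMA software, its version and the probe annotation it used are not given in the sources used here. The deposited intensity values were linear, not logarithms: the lowest value of an array lay between 11.34 and 12.88 and the highest between 48550 and 50754. The array medians lay between 139.1 and 143.2. The values were therefore taken to log2(value + 1) before any test, as fixed for that case before the data were examined, and fold changes are on that scale. Array values hold no sequencing depth, and the number of arrays limits the precision. Scan dates or slides were not used here, so batches could not be tested. The table held 0 columns of samples outside this series.

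Of 22690 probe sets, 64 were controls and were left out of all tests. Of the others, 20380 had 1 gene symbol in the platform annotation, 691 had several and 1555 had none, and genes were named only from probe sets with 1 symbol. Symbols were updated through the Entrez identifiers of a RefSeq gene table, which matched 12369 of 12393 genes; the other 24 kept the symbol of the annotation. For the 4956 genes with several probe sets, the probe set with the highest mean over the 7 arrays stood for the gene. Of the 82 named genes with several, 34 had another probe set with less than 50% of the reported log2 fold change or the opposite sign. No genome coordinates are given, since the files name no genome build.

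Groups came from the genotype label of each sample. The labels do not say whether each array came from a separate animal, and the p-values measure the spread between these samples. No pair of arrays was a duplicate: at most 1819 of 22690 probe sets had values equal in every digit given, with no rounding, in any pair. Wild type arrays 1 to 3 and knockout arrays 1 to 3 shared replicate numbers, and deviations from the group means did not follow them, so the fit reported has no pairing.

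The comparison of knockout with wild type was fitted per gene with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the 12393 genes and a threshold of 0.05 on the adjusted p. No filter on dim genes was used. Log2 fold changes are knockout minus wild type, given with standard errors (SE), and group means are given with standard deviations (SD). Yy1 was tested as well by an exact permutation test of the difference of means over the 35 ways of dividing 7 arrays into 3 and 4, whose smallest p is 0.0286.

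Before the data were examined, 45 gene lists were written from general knowledge of muscle: mitochondrial energy metabolism, glycolysis, slow and fast contractile genes, calcium handling, developmental, denervation, atrophy, autophagy, growth factor, stress, proliferation, matrix, ribosome and proteasome genes, partners of the YY1 protein, interferon and clock genes, and markers of other cell types and of sample quality. Together, 16 genes stood in more than 1 list. Each list with at least 5 measured members was tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over 44 lists. Members past the threshold were also counted with the p-values adjusted over the list alone. Camera with the correlation estimated from the data, and fry, a rotation test of whether a list's genes move one way, were run beside it.

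The genes named in the text were fixed by rule before the data were examined: Yy1; the 12 largest log2 fold changes in each direction among genes past the threshold with no overlap between the groups' values and a mean in the higher group above the median of all genes, passing over clone names; and, per list, up to 3 members in each direction with the smallest p, or, where none passed, the 2 with the smallest p as values. Genes named outside that rule are said to be chosen after their values were seen.

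The scripts were tested on simulated data: in 20 draws over 12393 genes with 200 changed, limma recovered 96.3% of genes changed by a log2 fold change of 1 and 69.5% of those changed by 0.5, and 4.59% of its calls were false. Camera called 100% of the shifted lists and 0.1 unshifted lists per draw. The genes were simulated as independent, while estimated correlations in the real lists reached 0.827, and 32.9% of the real genes passed the threshold. The draws check the scripts and do not give the rate of false calls in the real data.

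The alternatives tried were every probe set tested separately, the mean of a gene's probe sets, genes above the median level only, arrays centred on their median, repeated quantile normalization, a variance trend with robust fitting, array weights, a pseudocount of 16, stricter thresholds, each array left out in turn and the replicate number as a block. A permutation test of each list's mean per array was added after the results were seen. It and fry do not compare a list with the other genes, as camera does. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.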

Results

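Gene expression in the mouse soleus was measured on 7 arrays, 3 from wild type mice and 4 from mice labelled as knockout for Yy1, the gene of the zinc finger transcription factor Yin Yang 1. All mice were 6 months old, and each array gave 1 intensity for each of 22690 probe sets. Array medians lay between 139.1 and 143.2. Correlations of log2 values over the gene table were 0.9969 to 0.9973 within wild type, 0.9954 to 0.9969 within knockout and 0.9768 to 0.9873 between the genotypes. The first principal component held 77.9% of the variance and placed the wild type arrays between -28.8 and -26.1 and the knockout arrays between 12.6 and 26.9.

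Yy1 itself was lower in the knockout soleus. Its brightest probe set over the 7 arrays measured 9.38 ± 0.22 log2 units in wild type (SD, n = 3) and 8.35 ± 0.11 in knockout (SD, n = 4), a log2 fold change of -1.02 (SE 0.10, adjusted p = 0.000213) that left 49.2% of the wild type signal. The difference had a two-sided exact permutation p of 0.0286, the smallest that 3 arrays against 4 can give. A second probe set, the brightest of the 4 in wild type at 9.75 ± 0.10 (SD, n = 3), fell by 1.70 log2 units, to 30.7%. Another fell by 0.77, to 58.8% of wild type. The dimmest of the 4 probe sets, at 5.26 ± 0.19 in wild type (SD, n = 3), measured 5.20 ± 0.14 in knockout (SD, n = 4; log2 fold change -0.060, adjusted p = 0.711). Where these probe sets lie relative to the removed part of the gene is not given in the sources used here, so the remaining signal does not measure how many cells kept an intact gene.

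**Figure D1:**
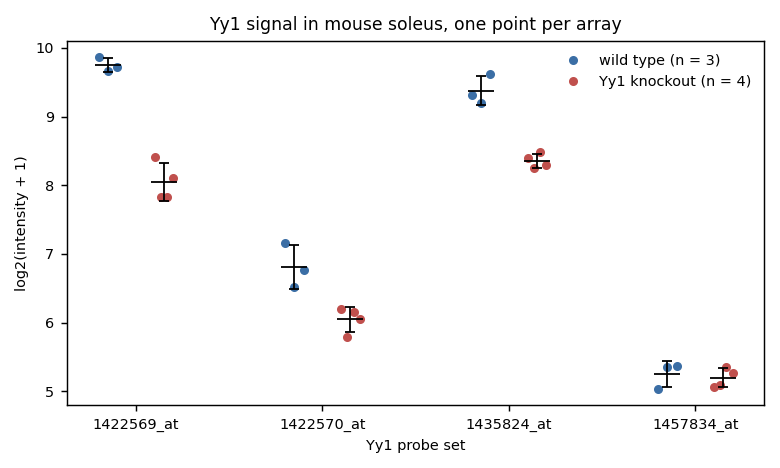
Signal of each Yy1 probe set on the 3 wild type and 4 knockout arrays, in log2(intensity + 1), 1 point per array, with the group mean and SD in black. In the 3 brighter probe sets every knockout array lies below every wild type array, while in the dimmest, at 5.26 in wild type and 5.20 in knockout, the groups overlap.

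Knockout soleus had lower transcripts of mitochondrial energy metabolism and of blood vessel endothelium. It had higher transcripts of developmental muscle, of the denervation and neuromuscular junction list, of macrophages and of extracellular matrix. The list tests behind these differences hold at camera's preset correlation between genes, and with an estimated one none does (adjusted p = 0.291 to 0.427). In all, 4082 of 12393 genes (32.9%) passed the threshold, 2103 higher and 1979 lower in knockout. The median size of these changes was 0.45 log2 units. A change of at least 2-fold was seen in 469 of them, 225 higher and 244 lower, and of at least 4-fold in 46 higher and 30 lower. The groups did not overlap at all in 4900 genes (39.5%), where chance gives 5.71%.

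By the brightest probe set of each gene, the largest rise was in Igf2, a growth factor of fetal growth and muscle regeneration, at 4.42 log2 units (SE 0.21, adjusted p = 2.88e-05) or 21.4-fold. A second, dimmer Igf2 probe set rose by 1.13. Ccl8, a chemokine that attracts monocytes, rose by 3.97 (SE 0.34, adjusted p = 0.000113), and Sln, whose product sarcolipin inhibits the calcium pump of the sarcoplasmic reticulum, by 3.81 (SE 0.29, adjusted p = 7.02e-05). Peg3, an imprinted zinc finger gene, rose by 3.43 (SE 0.24), Mybph, of myosin binding protein H, by 3.29 (SE 0.33) and Myh8, the perinatal myosin heavy chain, by 3.22 (SE 0.32). Periostin (Postn), a matrix protein, rose by 3.18 (SE 0.26) and C1qtnf3, of a secreted C1q/TNF-related protein, by 3.17 (SE 0.22). Myl4, the embryonic and atrial myosin light chain, rose by 2.86 (SE 0.20), as did the myogenic transcription factor Myog (SE 0.17). A dimmer probe set of Myl4 measured 0.07 (SE 0.06). Ankrd1, an ankyrin repeat protein of the stretched sarcomere, and Ndrg4 both rose by 2.82 (SE 0.20 and 0.33).

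The largest fall was in Dach2, a transcriptional corepressor known to hold down Myog in innervated muscle, at -4.27 (SE 0.22, adjusted p = 2.88e-05), 19.3-fold lower in knockout. Ephx2, the soluble epoxide hydrolase, changed by -3.17 (SE 0.32) and Grb14, an adaptor that inhibits the insulin receptor, by -3.16 (SE 0.38). Asb4 changed by -3.0 (SE 0.12), Plbd1 by -2.98 (SE 0.17), the water channel gene Aqp4 by -2.82 (SE 0.17) and the Wnt modulator Dkk2 by -2.81 (SE 0.21). The cytokine Il15 changed by -2.72 (SE 0.25), the mitochondrial enzyme gene Clybl by -2.57 (SE 0.23), the arsenite methyltransferase As3mt by -2.56 (SE 0.18), the chromatin protein Hmgb3 by -2.44 (SE 0.13) and Cth, of cystathionine gamma-lyase, by -2.42 (SE 0.28). Adjusted p lay between 2.43e-05 and 0.00044 for these 24 genes. The dimmest group means among them were those of Dach2 (5.46), Asb4 (5.09), Aqp4 (5.28) and Cth (5.46) in knockout and of C1qtnf3 (4.50) in wild type. No detection call was used, so background may limit the size of these fold changes.

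**Figure D2:**
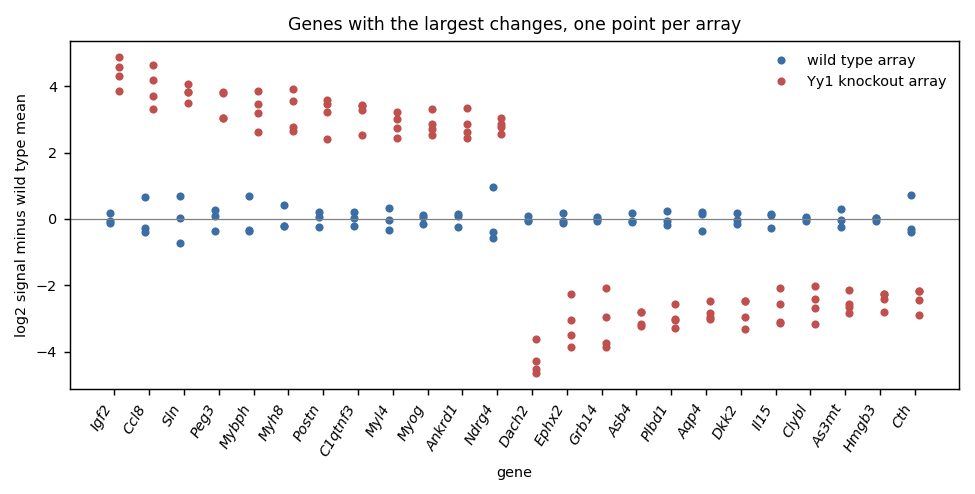
Log2 signal of the 24 genes with the largest changes on each array, minus the gene's wild type mean, with 1 point per array. Genes were picked for no overlap between the groups, so the gap between genotypes in every gene follows from the choice. Knockout means run from Igf2 at 4.42 above to Dach2 at -4.27. Wild type arrays centre on 0 by construction, with the widest spread in Ndrg4 (SD 0.84).

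Genes of fatty acid oxidation fell almost throughout. Of 20 measured, 19 fell and none rose (20 fell when adjusted over the list alone), with a median log2 fold change of -1.04. The list also held Cd36, Fabp3 and Lpl, genes of fatty acid supply. Hadha, of the trifunctional protein of beta-oxidation, changed by -1.46 (SE 0.10, adjusted p = 5.02e-05), the enoyl-CoA isomerase Eci1 by -1.39 (SE 0.12) and the enoyl-CoA hydratase Echs1 by -1.56 (SE 0.13). Camera gave adjusted p = 4.59e-13 for the list, and adjusted p = 0.379 with an estimated correlation. All 17 genes of the tricarboxylic acid cycle list fell (17 also when adjusted over the list alone), with a median of -0.50. This list also held Pdha1, Pdhb and Dlat, of pyruvate dehydrogenase, and the pyruvate carrier gene Mpc1. Suclg2, a subunit of succinyl-CoA ligase, changed by -2.22 (SE 0.22), Suclg1 by -0.81 (SE 0.08) and Idh3g, of NAD-dependent isocitrate dehydrogenase, by -0.59 (SE 0.06). The camera test gave adjusted p = 2.5e-09, and adjusted p = 0.379 with an estimated correlation.

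Subunits of the respiratory chain fell by smaller amounts. In complex I, 23 of 33 genes fell and none rose (24 fell when adjusted over the list alone; median -0.26), among them Ndufa3 (-0.71, SE 0.06), Ndufb5 (-0.66, SE 0.07) and Ndufa9 (-0.58, SE 0.06). For this list camera gave adjusted p = 4.82e-09 and adjusted p = 0.379 with an estimated correlation. In complexes II and III, 10 of 14 fell and none rose (11 adjusted over the list alone; median -0.40), with Uqcrc1 at -0.80 (SE 0.09), Sdha at -0.61 (SE 0.08) and Sdhb at -0.56 (SE 0.07). For complexes II and III camera gave adjusted p = 9.71e-06 and adjusted p = 0.379 with an estimated correlation. In complex V, the ATP synthase, 11 of 15 fell and none rose (12 adjusted over the list alone; median -0.31), with Atp5o at -0.70 (SE 0.07) and Atp5g1 at -0.56 (SE 0.07). By camera the list had adjusted p = 1e-05 and adjusted p = 0.379 with an estimated correlation. Complex IV moved least: 5 of 16 fell, 1 rose and 10 did not pass (7 fell and 1 rose when adjusted over the list alone; median -0.14). Cox7a1, the muscle form of subunit 7a, changed by -0.99 (SE 0.15) and Cox8a by -0.48 (SE 0.06), while Surf1, a complex IV assembly factor, rose by 0.38 (SE 0.06). For complex IV camera gave adjusted p = 0.0287, adjusted p = 0.427 with an estimated correlation, and adjusted p = 0.0722 over genes above the median level. It did not call the list with the replicate number as a block (adjusted p = 0.0655), nor did the permutation test of list means (adjusted p = 0.0718). The number of complex IV genes that fell was 2 without wild type array 2 and 3 without wild type array 1, wild type array 3, knockout array 3 or knockout array 4.

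Genes of the mitochondrial ribosome, which translates the proteins encoded by mitochondrial DNA, fell in 36 of 61 cases and 1 rose (37 and 1 when adjusted over the list alone; median -0.28). The gene that rose, Mrpl33, lost its call without wild type array 2 (adjusted p = 0.107) or 3 (0.124) or knockout array 2 (0.0778), 3 (0.0645) or 4 (0.0526). Mrpl23 changed by -0.80 (SE 0.06), Mrps5 by -0.83 (SE 0.07) and Mrpl27 by -0.69 (SE 0.06). For mitochondrial ribosome genes camera gave adjusted p = 5.51e-11 and adjusted p = 0.379 with an estimated correlation. Of 19 genes of mitochondrial import and protein quality control, 10 fell and 1 rose (14 and 1 adjusted over the list alone), with the protease subunit Clpp at -0.52 (SE 0.07), the import cochaperone Grpel1 at -0.43 (SE 0.06) and the translocase Timm17a at -0.52 (SE 0.08). The gene that rose, Tomm22, lost its call when any array except wild type array 2 was left out (adjusted p = 0.056 to 0.14) and with arrays centred on their median (0.0622) or its probe sets averaged (0.136). Tested with camera, the list had adjusted p = 4.2e-05 and adjusted p = 0.379 with an estimated correlation. Of 11 genes of mitochondrial fusion and fission, 7 fell and none rose (7 adjusted over the list alone), with the mitofusin Mfn1 at -1.04 (SE 0.11) and Opa1, of inner membrane fusion, at -0.69 (SE 0.07). Camera gave adjusted p = 0.00159 and adjusted p = 0.379 with an estimated correlation.

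Among 18 regulators of mitochondrial biogenesis, 9 fell and none rose (9 adjusted over the list alone; median -0.18). Ppara, a nuclear receptor of lipid oxidation genes, changed by -1.20 (SE 0.14, adjusted p = 0.000418) and the mitochondrial transcription factor Tfb2m by -0.57 (SE 0.09, adjusted p = 0.00142). Of 3 genes chosen after their values were seen, the coactivator gene Ppargc1a changed by -0.98 (SE 0.31, adjusted p = 0.0387), while Tfam measured 0.00 (SE 0.07, adjusted p = 0.987) and Nrf1 0.03 (SE 0.08, adjusted p = 0.803). For the regulators camera gave adjusted p = 0.0149 and adjusted p = 0.379 with an estimated correlation, and the number that fell was 5 without wild type array 2 or wild type array 3. The permutation test of list means did not call the regulators (adjusted p = 0.0718). Genes of glycolysis and glycogen metabolism also moved down: 9 of 17 fell and none rose (12 adjusted over the list alone; median -0.24), with hexokinase Hk2 at -0.84 (SE 0.10), muscle glycogen phosphorylase Pygm at -0.81 (SE 0.09) and the phosphorylase kinase subunit Phkg1 at -1.85 (SE 0.25). The camera test gave adjusted p = 2e-04 and adjusted p = 0.379 with an estimated correlation.

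**Figure D3:**
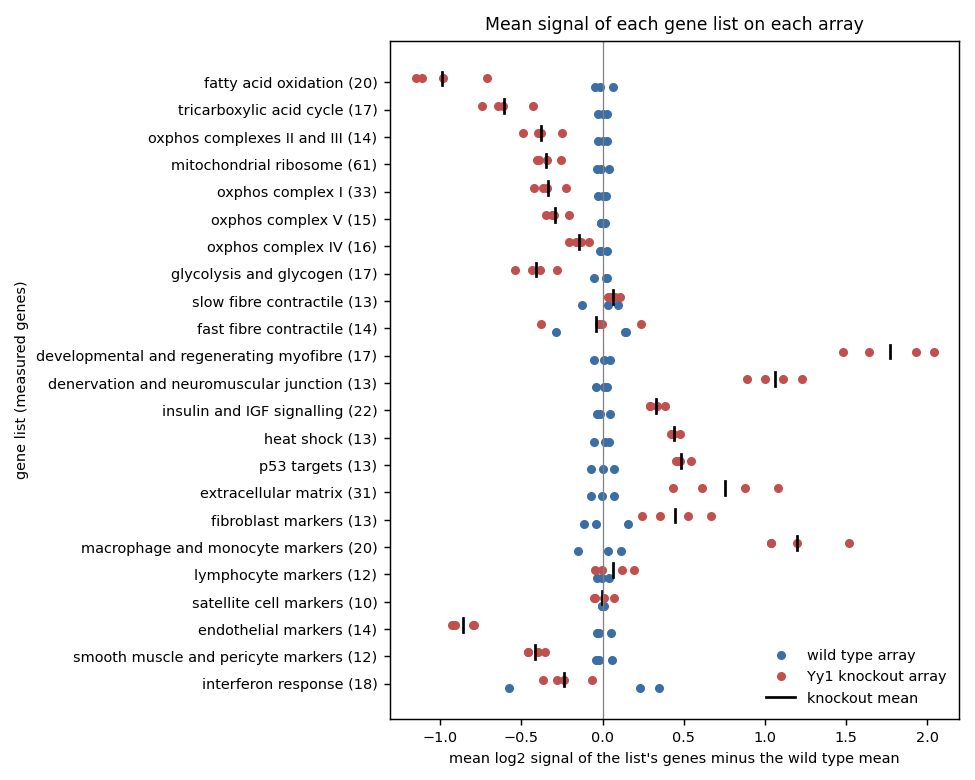
Mean log2 signal of the measured genes of selected lists on each array, minus the wild type mean of that list, with the knockout mean as a black bar and the number of genes in brackets. Fatty acid oxidation lies at -0.99 and endothelial markers at -0.86 in knockout, macrophage markers at 1.20 and developmental myofibre genes at 1.77, while interferon genes separate wild type array 1, at -0.58, from the other wild type arrays.

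More slow fibre genes rose than fell, and more fast fibre genes fell than rose. Of 13 slow fibre genes, 7 rose and 2 fell (9 and 2 adjusted over the list alone; median 0.17). The slow troponin Tnni1 rose by 0.40 (SE 0.06) and Csrp3, a Z-disc protein, by 0.72 (SE 0.15), while Pln, of the calcium pump inhibitor phospholamban, changed by -2.14 (SE 0.18) and the slow myosin light chain Myl3 by -0.26 (SE 0.06). Of 14 fast fibre genes, 7 fell and 1 rose (7 and 1 adjusted over the list alone; median -0.25), with the fast myosin heavy chain Myh2 at -0.46 (SE 0.11), the fast calcium pump Atp2a1 at -0.33 (SE 0.08), and Tpm1 at -0.42 (SE 0.08). Actn3, the alpha-actinin of fast fibres, rose by 2.10 (SE 0.34). For a rise of the slow genes camera gave adjusted p = 0.0498 and adjusted p = 0.549 with an estimated correlation. For a fall of the fast genes it gave adjusted p = 0.0388 and adjusted p = 0.554 with an estimated correlation. The slow list lost its call without wild type array 2 (adjusted p = 0.116), wild type array 3 (0.0529), knockout array 1 (0.0874) or knockout array 4 (0.0651), and the fast list without wild type array 2 (0.0905), wild type array 3 (0.0568) or knockout array 2 (0.0548). Neither list was called over genes above the median level (0.13 slow, 0.0924 fast), by fry (0.052 and 0.0956) or by a permutation test of list means chosen after the results were seen (unadjusted p = 0.343 and 0.886). With the replicate number as a block camera did not call the slow list (adjusted p = 0.0719). The slow genes that rose numbered 2 without wild type array 2 and 4 without wild type array 3 or knockout array 2, and the fast genes that fell numbered 3 without wild type array 2 or 3. In wild type, 6 slow and 7 fast genes measured above 15 log2 units, where the brightest value on any array was 15.63, so changes of these genes are read near the top of the scale.

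Genes of calcium handling went both ways. Of 13, 5 rose and 3 fell (6 and 4 adjusted over the list alone). Sln rose as above, the calcium channel subunit Cacnb1 rose by 0.46 (SE 0.08) and Asph, whose products include junctin, by 0.33 (SE 0.07). In contrast, the chloride channel Clcn1 changed by -0.74 (SE 0.08), the voltage sensor Cacna1s by -0.55 (SE 0.11) and the junctophilin Jph1 by -0.41 (SE 0.09). The list's median was -0.04 and its mean 0.26, and camera pointed up without a call (adjusted p = 0.839), while the permutation test of the mean gave adjusted p = 0.0419. The mean was carried mostly by Sln, at 3.81.

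Genes of developing and regenerating fibres rose in 15 of 17 cases and none fell (15 adjusted over the list alone; median 2.0). Beside Igf2 and Myog, the neural cell adhesion molecule Ncam1 rose by 2.12 (SE 0.14, adjusted p = 5.02e-05). For this list camera gave adjusted p = 5.51e-11 and adjusted p = 0.379 with an estimated correlation. Of 13 genes of denervation and the neuromuscular junction, which share Myog, Ncam1 and the fetal acetylcholine receptor subunit gene Chrng with that list, 11 rose and 1 fell (11 and 1 adjusted over the list alone; median 0.85). Runx1, a transcription factor that rises in denervated muscle, was up by 2.43 (SE 0.13, adjusted p = 2.93e-05; -0.12 to 1.58 in its 4 other probe sets), while Musk, the receptor kinase that organises the junction, changed by -0.61 (SE 0.08, adjusted p = 0.000532). By camera the list had adjusted p = 1.29e-05 and adjusted p = 0.379 with an estimated correlation. Loss of the nerve was not measured, so these genes do not by themselves show denervation. Satellite cell markers did not move as a list (1 of 10 rose, 2 fell, and the same counts adjusted over the list alone; camera adjusted p = 0.928): Myf5 rose by 0.52 (SE 0.10), Chrdl2 changed by -0.96 (SE 0.12) and Sdc4 by -0.31 (SE 0.07).

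In insulin and IGF signalling, 11 of 22 genes rose and 2 fell (11 and 2 adjusted over the list alone; median 0.33). The receptor substrate Irs1 rose by 0.96 (SE 0.09) and the kinase subunit Pik3ca by 0.45 (SE 0.05), beside Igf2. Grb14 and Tsc2 (-0.26, SE 0.07) were lower. Tsc2 lost its call, leaving 1 gene lower, without wild type array 1 (adjusted p = 0.0722) or wild type array 3 (0.0717). Tested with camera, the list had adjusted p = 0.00697 and adjusted p = 0.379 with an estimated correlation. Targets of p53 rose in 8 of 13 cases and 1 fell (8 and 1 adjusted over the list alone; median 0.46), with the cell cycle inhibitor Cdkn1a at 2.29 (SE 0.18, adjusted p = 7.57e-05), Zmat3 at 0.78 (SE 0.08), Mdm2 at 0.56 (SE 0.07) and Ccng1 at -0.66 (SE 0.13). Camera gave adjusted p = 0.00183 and adjusted p = 0.379 with an estimated correlation. Of 22 proliferation genes, 9 rose and none fell (9 adjusted over the list alone; median 0.23), with Birc5 at 0.73 (SE 0.06), Mcm7 at 0.73 (SE 0.08) and Mcm4 at 0.59 (SE 0.07); 5 rose without wild type array 2 or wild type array 3. The camera test gave adjusted p = 0.00221 and adjusted p = 0.379 with an estimated correlation.

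Heat shock genes rose in 8 of 13 cases and none fell (10 adjusted over the list alone; median 0.28), with the small heat shock proteins Hspb8 at 1.16 (SE 0.07) and Hspb1 at 0.94 (SE 0.10) and the chaperone Hsp90aa1 at 0.69 (SE 0.08). For this list camera gave adjusted p = 0.000412 and adjusted p = 0.291 with an estimated correlation. In the unfolded protein response of the endoplasmic reticulum, 6 of 16 rose and 1 fell (6 and 1 adjusted over the list alone; median 0.14), with the disulfide isomerase Pdia6 at 0.46 (SE 0.07) and Dnajb9 at 0.34 (SE 0.07). The gene that fell, Herpud1, lost its call without wild type array 2 (adjusted p = 0.132) or 3 (0.143) or knockout array 2 (0.1), 3 (0.069) or 4 (0.0943). By camera the list had adjusted p = 0.028 and adjusted p = 0.379 with an estimated correlation, and the unfolded protein list was not called without knockout array 1 (adjusted p = 0.0655). In the integrated stress response, 9 of 27 genes rose and 2 fell (9 and 2 adjusted over the list alone; median 0.20). Camera did not call this list (adjusted p = 0.0827), while fry called it upward (0.00906), as did the permutation test (0.0419). The mitochondrial folate enzyme Mthfd2 rose by 1.47 (SE 0.11), the amino acid transporter Slc7a5 by 1.11 (SE 0.13) and Aldh18a1, of proline synthesis, by 0.97 (SE 0.14), while Chac1, which degrades glutathione, changed by -1.36 (SE 0.17). Oxidative stress genes split, 6 of 20 higher and 8 lower (6 and 8 adjusted over the list alone; camera adjusted p = 0.428), and fry (0.0481) and the permutation test (0.0419) called the list downward. Gpx1 rose by 1.45 (SE 0.10), thioredoxin Txn1 by 0.78 (SE 0.08) and Gclm by 0.62 (SE 0.06). Ucp3 changed by -1.79 (SE 0.14), Gsta4 by -1.37 (SE 0.13) and Prdx3 by -0.91 (SE 0.09).

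Cytosolic ribosomal protein genes rose in 14 of 30 cases and none fell (16 adjusted over the list alone; median 0.20), with Rpl14 at 0.43 (SE 0.07), Rpl7 at 0.41 (SE 0.07) and Rps14 at 0.38 (SE 0.06); 8 rose without wild type array 2. Tested with camera, the list had adjusted p = 2.26e-05 and adjusted p = 0.382 with an estimated correlation. Of 32 proteasome genes, 11 rose and 3 fell (11 and 3 adjusted over the list alone; median 0.11), with the regulatory subunits Psmd8 at 0.70 (SE 0.08) and Psmd13 at 0.64 (SE 0.06) and the proteasome activator Psme1, an interferon-inducible gene, at -1.09 (SE 0.08). Camera gave adjusted p = 0.0276 and adjusted p = 0.408 with an estimated correlation, and 1 proteasome gene fell without wild type array 2 or wild type array 3. With the replicate number as a block camera did not call the proteasome list (adjusted p = 0.0719). Atrophy genes split into 4 of 12 higher and 4 lower (5 and 5 adjusted over the list alone), with the metallothioneins Mt2 at 2.76 (SE 0.27) and Mt1 at 1.17 (SE 0.22) against the ubiquitin ligase gene Fbxo32 at -0.50 (SE 0.10) and Klf15 at -0.56 (SE 0.11). The atrophy list had a median of 0.03 and a mean of 0.20, while camera pointed down without a call (adjusted p = 0.946). Autophagy genes split into 3 of 17 higher and 3 lower (3 and 4 adjusted over the list alone; camera adjusted p = 0.602), with Gabarap at 0.42 (SE 0.05), Lamp2 at 0.39 (SE 0.07), Map1lc3b at -0.48 (SE 0.06) and Atg4b at -0.36 (SE 0.07).

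Markers of macrophages and monocytes rose in 20 of 20 cases (20 adjusted over the list alone; median 1.23). Cd68, of the macrophage lysosome, rose by 2.05 (SE 0.13, adjusted p = 4.33e-05), the protease Ctss by 2.06 (SE 0.15) and Laptm5 by 1.52 (SE 0.14). The camera test gave adjusted p = 9.65e-11 and adjusted p = 0.379 with an estimated correlation. None of 12 lymphocyte markers passed (0 adjusted over the list alone; camera adjusted p = 0.61), with Nkg7 at 0.31 (SE 0.12, adjusted p = 0.083) and Cd3d at 0.10 (SE 0.10, adjusted p = 0.494). Nkg7 passed without wild type array 1 (0.0337) or knockout array 1 (0.0489). Of 10 granulocyte markers Mmp9 passed upward (0.19, SE 0.06) and S100a9 downward (-0.57, SE 0.18) over all genes, and 0 passed adjusted over the list alone (camera adjusted p = 0.322). Both lost their calls without wild type array 1 (0.0531 and 0.139), wild type array 2 (0.147 and 0.116) or knockout arrays 1 (0.0922 and 0.0583), 2 (0.0994 and 0.0525) or 3 (0.0554 and 0.0713). Mmp9 lost it also without wild type array 3 (0.123) and with arrays centred on their median (0.0676), and its other, dimmer probe set changed by -0.19, so that the mean of both gave a log2 fold change of 0.0004 (adjusted p = 0.995). The call of S100a9 was lost also without knockout array 4 (0.0822). The permutation test called a fall of the granulocyte list (adjusted p = 0.0419).

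Extracellular matrix genes rose in 20 of 31 cases and 2 fell (20 and 2 adjusted over the list alone; median 0.74), alongside the macrophage markers. Lgals3, of galectin 3, a lectin abundant in macrophages, rose by 2.44 (SE 0.16) and Ccn2, of connective tissue growth factor, by 1.20 (SE 0.08), beside Postn. The basement membrane collagen Col4a1 changed by -0.66 (SE 0.13), and it was the only matrix gene that fell without wild type array 2 or wild type array 3. For this list camera gave adjusted p = 9.71e-06 and adjusted p = 0.427 with an estimated correlation. Fibroblast markers rose in 8 of 13 cases and none fell (8 adjusted over the list alone; median 0.46), with Col1a1 at 0.96 (SE 0.16) and dermatopontin (Dpt) at 0.46 (SE 0.10). Of the fibroblast markers, 3 rose without wild type array 1 and 5 without wild type array 2 or knockout array 2. By camera the list had adjusted p = 0.00106 and adjusted p = 0.408 with an estimated correlation. The permutation test did not call the fibroblast list (adjusted p = 0.0718). Of 9 tendon markers, 4 rose and 1 fell (4 and 2 adjusted over the list alone), with Comp at 1.75 (SE 0.15), Thbs4 at 1.19 (SE 0.20) and Scx at 0.74 (SE 0.12), and camera did not call the list (adjusted p = 0.0908). Camera over genes above the median level (0.0214), fry (0.0143) and the permutation test (0.0419) called it upward. The tendon gene that fell, Kera, lost its call without wild type array 1 (0.069) or 2 (0.0727) or knockout array 2 (0.0548), 3 (0.0513) or 4 (0.0528).

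Endothelial markers moved in the opposite direction to those of macrophages: 12 of 14 fell and none rose (13 adjusted over the list alone; median -0.91). The endothelial cadherin Cdh5 changed by -1.04 (SE 0.08, adjusted p = 6.01e-05), the receptor Tie1 by -0.96 (SE 0.07) and Robo4 by -1.05 (SE 0.08). Tested with camera, the list had adjusted p = 3.82e-10 and adjusted p = 0.291 with an estimated correlation. Smooth muscle and pericyte markers fell in 7 of 12 cases and 2 rose (7 and 2 adjusted over the list alone; median -0.51), with the pericyte genes Kcnj8 at -1.64 (SE 0.08), Rgs5 at -0.91 (SE 0.08) and Abcc9 at -0.65 (SE 0.06). Cspg4 rose by 0.73 (SE 0.10) and desmin (Des), which muscle fibres also express, by 0.54 (SE 0.05). Camera gave adjusted p = 0.0045 and adjusted p = 0.379 with an estimated correlation. Of 14 angiogenesis and hypoxia genes, 5 fell and 1 rose (8 and 1 adjusted over the list alone; median -0.22), with the growth factors Vegfa at -1.30 (SE 0.14) and Vegfb at -1.08 (SE 0.12), the transcription factor Epas1 at -1.05 (SE 0.08) and Pfkfb3 at 0.76 (SE 0.17). The camera test gave adjusted p = 0.0137 and adjusted p = 0.379 with an estimated correlation, and over genes above the median level it did not call the list (adjusted p = 0.163). Without wild type array 3, 3 angiogenesis genes fell, and 2 rose without knockout array 3.

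Adipocyte markers fell in 5 of 10 cases and 1 rose (6 and 2 adjusted over the list alone; median -0.77), with Pparg at -0.81 (SE 0.08), Fabp4 at -0.72 (SE 0.09), Cidea at -0.98 (SE 0.14) and resistin (Retn) at 1.06 (SE 0.21). For this list camera gave adjusted p = 0.0356 and adjusted p = 0.427 with an estimated correlation, and the adipocyte list was not called without wild type array 3 (adjusted p = 0.0631) or over genes above the median level (0.327). Of 9 Schwann cell and nerve markers, the myelin gene Mbp changed by -1.73 (SE 0.31, adjusted p = 0.00334; -1.37 to -0.23 in its 7 other probe sets) and 8 did not pass (1 adjusted over the list alone; camera adjusted p = 0.602); 2 passed without wild type array 2. Of 6 erythrocyte markers 2 fell (3 adjusted over the list alone; camera adjusted p = 0.234), Bpgm at -0.67 (SE 0.07) and Alas2 at -0.70 (SE 0.19); 1 fell without wild type array 1, wild type array 3 or knockout array 2. Fry (adjusted p = 0.00906) and the permutation test (0.0419) called a fall of the erythrocyte list.

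Partners of the YY1 protein were not called as a list. Of 21, 3 rose and 1 fell over all genes (1 and 1 adjusted over the list alone; camera adjusted p = 0.6), with Ino80c, of the INO80 chromatin remodeller, at 0.36 (SE 0.07) and Rnf2, of polycomb repressive complex 1, at -0.48 (SE 0.10). The partner genes that rose numbered 1 when any of wild type arrays 1 and 2 and knockout arrays 1, 2 and 4 was left out, and 2 fell without knockout array 4. Of 16 clock genes only Clock passed over all genes (0.40, SE 0.10, adjusted p = 0.0156), and 0 passed adjusted over the list alone (camera adjusted p = 0.794); Clock did not pass without wild type array 1 (0.0549) or wild type array 3 (0.0643), and 1 clock gene was lower without wild type array 2 or knockout array 1. Of 16 immediate early genes, which mark handling of the tissue, 3 passed upward and 3 downward (3 and 3 adjusted over the list alone; camera adjusted p = 0.652), with Myc at 0.71 (SE 0.16) and Nr4a1 at -0.88 (SE 0.17). Of the immediate early genes, 1 was higher without wild type array 2, and 1 was lower when any of wild type arrays 1, 2 and 3 and knockout arrays 3 and 4 was left out. Interferon response genes were not called (2 of 18 lower, 1 adjusted over the list alone; camera adjusted p = 0.194), and Rsad2 changed by -0.79 (SE 0.14). The interferon result rested on wild type array 1: without it 9 genes were lower and camera gave adjusted p = 1.42e-05, and 1 was lower when any other array was left out. Of 4 measured sex-linked genes, too few for a list test, the Y-linked Uty changed by -0.55 (SE 0.11) and 3 did not pass. Adjusted over the list alone 1 was lower, and without knockout array 1 over all genes 2 were lower. The other, dimmer Uty probe set changed by -0.12 (limma adjusted p = 0.4765 over all probe sets). The sex of the animals is not given in the sources used here.

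RNA quality measures differed a little between the genotypes. The ratio of 3' to 5' signal was 0.97 ± 0.0092 in wild type and 1.01 ± 0.023 in knockout for Gapdh, and 1.06 ± 0.012 and 1.11 ± 0.040 for Actb (SD, n = 3 and n = 4). The Gapdh ratio of every knockout array lay above those of wild type. With camera's preset correlation 29 of 44 lists were called, 13 up and 16 down, and 0 were called with an estimated correlation, where 4 lists had an unadjusted p under 0.05; fry called 31, of which 27 were the same lists in the same direction. All camera calls above therefore hold with a preset correlation and none holds with an estimated one.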

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

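The count of genes over the other splits, the grouping of the splits and both dilution tests were chosen after the results they bear on had been seen; the other tests were written beforehand. Of 35 splits of the 7 arrays into 3 and 4, the real split alone called 4082 genes and the highest of the others called 1. The real split is always among the 35, so 1 of 35 is the lowest share this test can give. The other splits mix the genotypes, whose difference then adds to the spread within groups, so few calls there follow from the design. The test cannot exclude chance or a batch shared by a genotype. For the gene lists, 1 of 35 splits called as many as the real 29, but the highest of the others called 26 and their median was 15.5, so camera at a preset correlation also calls many lists in other splits. These still hold part of the genotype difference: 22 to 26 lists were called in the 4 splits with every wild type array in the group of 4, 11 to 24 in the 12 with 2 wild type arrays in the group of 3, and 0 to 18 in the 18 with 1.

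Genes of fatty acid oxidation had a median log2 fold change of -1.04. Dilution of fibre RNA by RNA of other cells would lower other fibre genes as far. However, 20 contractile and calcium handling genes with a wild type mean under 14 log2 units had a median of 0.12. This is 1.16 above that of fatty acid oxidation (95% interval 0.72 to 1.54, bootstrap over genes). A first version over all 27 contractile genes, 18 of them brighter than that limit, gave 1.09. Some of the 20 genes changed in knockout themselves, among them Sln (3.81), Actn3 (2.10), Pln (-2.14) and Clcn1 (-0.74). A rise of such genes could mask dilution, so the test does not exclude it. The bootstrap resamples genes as if independent, and not arrays, while fatty acid oxidation genes had an estimated correlation of 0.827. The interval is therefore too narrow and leaves out the spread between arrays. A loss of signal in bright probe sets was tested with 10000 random lists of matched brightness, of which 0% had a median as low (range -0.44 to 0.31). Random lists hold unrelated genes, so they do not carry the correlation within the list. A lower level of these transcripts in the fibres is 1 explanation left open; a direct effect of Yy1 loss was not told apart from the state of the tissue. The shift in RNA quality measures and a batch shared by a genotype, of which the sources used here give no record, were not tested as causes.

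Endothelial markers were lower (median -0.91) while macrophage markers were higher (median 1.23). Dilution by RNA of infiltrating cells would lower genes of all resident cells alike, but the endothelial median lay at -0.872 (bootstrap 95% interval -1.06 to -0.608) relative to 61 genes of fibres under 14 log2 units and of satellite, Schwann, smooth muscle, pericyte and fat cells; a first version against 22 fibroblast and Schwann cell markers gave -1.09. The medians of fibre (0.12), satellite (0.040) and Schwann cell (-0.035) genes lay near 0, while smooth muscle and pericyte (-0.51) and adipocyte markers (-0.77) fell too, and the endothelial median lay below theirs by less than the interval (-0.407, -0.947 to 0.0255, and -0.144, -1.04 to 0.0839). Of 10000 random lists of matched brightness 0% had a median as low (range -0.48 to 0.44). The bootstrap intervals again resample genes as if independent, and not arrays, so they are too narrow. The random lists again do not carry the correlation within the list. The fibre genes used as reference again include genes that changed in knockout themselves. A smaller share of endothelial cells in knockout soleus is a hypothesis that these values leave open, alone or with the cells around vessels, as is lower expression of the markers in the same number of cells.

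The mice had a mixed background, so DNA of the 129 strain carried along beside the deleted gene could have changed genes near Yy1. Of the 50 measured genes nearest to it, 22% passed the threshold (exact 95% interval 11.5% to 36%), against 33% of all other genes (two-sided Fisher's exact test, p = 0.13). The neighbours did not hold more changed genes than the rest. The test covers only these 50 genes. It cannot say how many of the 4082 genes a longer stretch, or a changed neighbour acting on genes elsewhere, could account for. The 11 neighbours that passed include Serpina1b (-1.82), Meg3 (1.67), Rian (0.96), Slc25a29 (-0.63) and Hsp90aa1 (0.69), named above among the heat shock genes. For single genes there carried-along DNA stays open. A strain difference elsewhere in the genome was not tested.

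Single knockout arrays stood apart from the other 3 by Dixon's criterion at 95% in 9 of 180 named genes, and chance alone picks out about 1 in 20. C1qtnf3 measured 7.04 on knockout array 1 against 7.79 to 7.95 on the others and 4.50 in wild type. On the same array Myl3 measured 15.26 against 15.12 to 15.14, Gpx1 12.26 against 12.57 to 12.59 and Gsn 13.67 against 13.82 to 13.83. On knockout array 2 Myl6b measured 7.42 against 6.98 to 7.05, Mdm2 10.21 against 9.98 to 10.01 and Nr4a1 9.66 against 10.36 to 10.40. On knockout array 3 Col1a1 measured 9.96 against 9.27 to 9.38, and on knockout array 4 Mthfd2 measured 8.99 against 9.39 to 9.46. Knockout array 1 showed 84.8% of the mean shift over the genes past the threshold, and arrays 2, 3 and 4 showed 112%, 104% and 99.6%.

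Data outside the gene table also held differences. Of 1555 probe sets with no gene named, 304 passed the threshold, 146 higher and 158 lower in knockout. Of 691 with several genes named, 204 passed, 136 higher and 68 lower. The control probe set for 18S ribosomal RNA measured a mean of 14.42 log2 units in knockout and 14.19 in wild type, with no overlap between the groups.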

How the results depend on the processing

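The permutation test of list means was chosen after the results were seen; the other alternatives were planned. Testing every probe set separately called 6477 of 22626, 3240 higher and 3237 lower, since more features were tested. Requiring a 2-fold change left 469 genes (225 higher, 244 lower), and an adjusted p under 0.01 left 2537 (1257 higher, 1280 lower). With all 7 arrays and no block, the other fits called 3228 to 4195 of the genes tested, the lowest with only the 6196 genes above the median level, of which 2962 were among the 4082; the mean of a gene's probe sets called 4112, of which 3715 were. Leaving out single arrays called 3171 genes (without wild type array 2) to 3962 (without knockout array 1) and 26 to 30 lists. The Yy1 change stayed past the threshold in each, while the dimmest Yy1 probe set gave -0.060. With an estimated correlation 0 lists were called. Camera then counts correlated genes as fewer independent ones, but this does not account for every lost call. Heat shock genes had an estimated correlation of 0.0043, below the preset 0.01. Their unadjusted camera p still rose from 0.00014 to 0.0111. With an estimated correlation camera also refers its statistic to the few residual degrees of freedom of 7 arrays, not to those of all genes. The lost calls therefore do not by themselves show that correlation between genes removes the differences. The share of each part was not tested. Exact permutation tests of list means per array (two-sided) called 30 of 44 lists at adjusted p = 0.0419, all at the smallest p of 0.0286, of which 24 were lists camera called in the same direction; complex IV, biogenesis regulators, fibroblast markers, slow fibre and fast fibre genes were not among them. The other 6 were calcium handling and integrated stress response (up), tendon (up), oxidative stress, granulocyte and erythrocyte lists (down). The rise of the calcium handling mean was carried mostly by Sln. The permutation test and fry ask whether a list moved, not whether it moved more than other genes. Since 39.5% of all genes separated the groups fully, and no random lists were put through these tests, their calls do not set a list apart. Fry did not call slow fibre (adjusted p = 0.052) or fast fibre genes (0.0956), and gained the stress response, tendon, oxidative stress and erythrocyte lists. Genes above the median level lost complex IV, slow and fast fibre, angiogenesis and adipocyte lists and gained tendon. Only 38 lists kept at least 5 genes there, of which 24 were called, 23 of them also called over all genes. The lists not tested there include a list called over all genes. Replicate numbers did not pair the arrays (correlations of deviations 0.0295, -0.126 and 0.0166 for numbers 1, 2 and 3). With the number as a replicate block over 6 arrays 3224 genes were called, against 3566 without it on the same arrays, and 26 lists, without complex IV (0.0655), slow fibre (0.0719) and proteasome (0.0719). Of 180 named genes 24 lost their call without some array and 0 changed direction. Contractile and respiratory chain genes lie near the top of the signal range, and probe sets near the lowest values are limited by background.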

Other observations

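The genes in the next sentences were chosen after their values were seen; the test of imprinted genes was written beforehand. Of 4 genes of antigen presentation by MHC class II, for which no list was written or tested, H2-Aa rose by 2.12 (SE 0.16, adjusted p = 6.27e-05), H2-Ab1 by 2.09 (SE 0.16, adjusted p = 6.66e-05), H2-Eb1 by 1.80 (SE 0.14, adjusted p = 8.13e-05) and the invariant chain Cd74 by 1.67 (SE 0.17, adjusted p = 0.000203). Mpeg1, a pore-forming protein of macrophages, rose by 2.52 (SE 0.17, adjusted p = 5.15e-05).

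Igf2, Peg3 and Asb4, which are imprinted, were among the largest changes, and the hypothesis that imprinted genes change more often than others was tested on imprinted genes other than 5 already seen. Of 37 measured, 14 passed the threshold, 11 higher and 3 lower, against a median of 12 in random lists of matched brightness. Only 70.9% of 10000 such lists held fewer, so the hypothesis was not borne out. Meg3 rose by 1.67 (SE 0.20) and Rian, of the same imprinted cluster, by 0.96 (SE 0.14), while Dlk1 beside them measured 0.25 (SE 0.14, adjusted p = 0.212). Dlk1, Meg3 and Rian are also the measured genes 4, 5 and 6 on one side of Yy1, among the neighbours tested for carried-along DNA.

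Interferon genes varied within wild type. The mean of the 18 genes on wild type arrays 1, 2 and 3 was -0.58, 0.35 and 0.23 relative to the wild type mean, and on knockout arrays 1 to 4 it was -0.24, -0.28, -0.07 and -0.37. Dach2 measured 9.73 ± 0.07 in wild type (SD, n = 3) and 5.46 ± 0.46 in knockout (SD, n = 4), and Myog, which it represses, 7.48 ± 0.14 and 10.34 ± 0.33.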
